A study of Mus musculus with 12 samples.

How the data were processed

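RNA of the lumbar spinal cord was sequenced from 12 mice in 4 groups of 3. Group H held healthy wild-type mice (H1, H2 and H4). The other 3 groups held mice of an amyotrophic lateral sclerosis (ALS) model whose strain is not given in the sources used here. Group P received phosphate-buffered saline (P66, P67 and P74), group C received manganese-doped carbon dots (C79, C84 and C85), and group E was read as the edaravone group (E75, E77 and E90). The series text lists a code E among the groups but describes edaravone under a code D, so E was assigned to edaravone by elimination. The number in each name is the mouse number of the label. Each number marks a separate mouse, so the libraries of a group are biological replicates per the labels, and no number is shared between groups.

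Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was captured on oligo(dT) beads, fragmented and reverse transcribed with random primers, and the second strand was made in a strand-marking buffer. Per the submitters' processing notes, cutadapt, HISAT2, featureCounts and the mouse build GRCm38 were used. Their versions, roles and strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart here.

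The authors deposited 4 tables, 1 per group, of FPKM values (fragments or reads per kilobase of exon, scaled to the mapped reads) for 33906 gene identifiers. The tables name no unit, and FPKM was settled from the values. Once multiplied by the union exon length of each gene in GENCODE M21, 95.2 to 95.7% of the low values (up to 50 multiples) lay within 0.02 of a whole multiple of 1 value per library. That step gave scaling totals of 15.5 to 18.4 M reads per library. The reads recovered over all genes summed to 16.8 to 19.8 M, 106.6 to 108.0% of the scaling total, and the reason for the excess was not resolved. Whether reads or fragments were counted is not known. A value of 1 read in a gene of 1 kb was 0.0542 to 0.0643 FPKM. Symbols, coordinates and lengths came from GENCODE M21 on GRCm38, which matched 33829 identifiers (14 symbols are shared by several identifiers). 945 genes were listed at 0 in every library. An exact 0 may be a failed estimate, since Mt2 is listed at or near 0 in all libraries, so such genes are given only as listed at 0.

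The design fixed before the data were examined assumed counts and a quasi-likelihood count test. FPKM values are not counts, so edgeR and DESeq2 were not used, and the tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). Every fold change is on that scale, which understates changes of low genes. A model with 1 mean per group was fitted to all 12 libraries (8 residual degrees of freedom), with limma's trended, robust moderation of variances and Benjamini-Hochberg adjustment within a comparison. The threshold was an adjusted p of 0.05. All p-values are two-sided. The filter of the design was applied to the recovered reads by hand. A gene was tested with at least 10 reads (as CPM in the median library) in at least 3 libraries and at least 15 reads in all. It left 18119 genes and set aside 15787. An FPKM filter had been tried first, its results were seen, and it is now an alternative. Further scaling was not applied.

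On simulated data for C against P over 18119 genes, the test recovered 74 of 100 genes changed by 2-fold and 99 of 100 changed by 4-fold, with 9 false calls. The changed genes were drawn only from genes with many reads, and genes were simulated independently. The recovery therefore does not cover genes near the filter or differences between mice that many genes share. The median standard error of a log2 fold change was 0.116, and the median 95% confidence interval reached 0.253 to either side. A permutation test of 3 against 3 values cannot give a p below 0.1.

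The rule for named genes was fixed before the data were examined. For P against H, C against P and E against P it took the 6 largest changes in each direction among genes that passed, with a mean log2 CPM of at least 1 and no overlap between the groups. From each list it took up to 3 members of smallest adjusted p that passed. Gene models without a given name were left out of the first part. Where no gene passed the first part, the 5 genes of smallest p in each direction were named as not passing. The superoxide and peroxide enzymes could be named whatever their test gave. Genes named for other comparisons, and the gene model Gm10479, were chosen after their values were seen. Values of some single genes are not reported here.

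Of 44 gene lists fixed before the data were examined, 43 had at least 4 tested members and were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists. The adipocyte list had 2 tested members and was not tested. Counts of members that passed are given over all genes and adjusted over the list alone. A list score is the mean log2(FPKM + 1) of its tested members in a library.

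For the comparison of treatment with disease changes, covariances across genes were set beside 100 simulations of counts without group effects. A slope of treatment on disease changes was computed with each P library held out in turn. Correlations over 12 libraries used deviations from group means, with 100000 permutations. The correlation over the 9 ALS model libraries used the scores as they are, with exact enumeration of all orders. The alternatives fixed in advance were limma-voom on recovered reads, median-ratio scaling, library size only, no filter, only the 2 groups compared, leaving out each library, an estimated correlation for camera, and fry. Added after seeing the data were a pseudocount of 0.1, an FPKM filter of 0.5, removal of each library's trend on exon length and GC content, covariates for nerve root content and for caudal Hox genes, and a slope through 0.

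Several other choices were made after values had been seen. The reversal slope was first taken through 0 and the simulation first used normal noise. A slope on the other P libraries was dropped because outcome and predictor were not independent. The enzymes listed were narrowed to 4 and then restored to 18. The caudal Hox genes were listed after Hoxc12 had been noticed among the C against E calls, and the rostral Hox genes before their values were seen. 2 explanations (the microglia and motor neuron relation, and a smaller share of all neurons) first came out as excluded, and the requirement that every leave-one-out value must pass as well was added after that.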

Results

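Gene expression in the lumbar spinal cord was measured by poly(A) RNA sequencing in 12 mice, 3 in each of 4 groups. Healthy wild-type mice (H) were compared with mice of an ALS model that received phosphate-buffered saline (P), manganese-doped carbon dots (C) or, as read from the labels by elimination, edaravone (E). ALS is a fatal disease in which motor neurons degenerate. The carbon dots are a nanozyme, a particle with enzyme-like activity, here one like that of superoxide dismutase per the series title, and edaravone is a radical scavenger used to treat ALS. The recovered reads summed to 16.8 to 19.8 M per library, and 18119 genes were tested. Fold changes are on the log2(FPKM + 1) scale and follow gene names as value ± standard error, with n = 3 mice per group. Means of FPKM are given ± SD, and coordinates are those of GRCm38.

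The first 3 principal components held 47.0, 16.9 and 8.09% of the variance. On the first, the healthy libraries lay between -46.3 and -30.3, and every ALS model library lay above them. Among the saline libraries, P74 lay nearest to the healthy libraries, at -4.72, against 30.7 for P66 and 15.8 for P67. Replicates were separate libraries, with 5.08 to 50.5 for their chi-square per degree of freedom and correlations of log2 values across genes of 0.966 to 0.993.

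The comparison of P with H asks what the disease model changes in the cord. Genes of activated glia rose most. Cst7, a protease inhibitor of activated microglia, had 0.273 ± 0.373 FPKM in H and 32.2 ± 14.5 in P (4.64 ± 0.34, adjusted p = 7.95e-05). Clec7a, a receptor for fungal glucans that is annotated as a polymorphic pseudogene in this assembly, differed by 4.63 ± 0.31 (adjusted p = 4.83e-05). Gpnmb (3.85 ± 0.51, adjusted p = 0.00164), Lgals3 (3.66 ± 0.33, adjusted p = 0.00019) and Lyz2 (4.04 ± 0.38, adjusted p = 0.000245) also rose, as did the acute-phase protease inhibitor Serpina3n (3.93 ± 0.35, adjusted p = 0.00019). Of 28 tested genes of disease-associated microglia, 24 rose, or 27 adjusted over the list alone (median 2.14). 13 of 14 complement genes rose, also 13 adjusted over the list alone (median 2.37). Among them were C4b, a component of the classical pathway (2.97 ± 0.18, adjusted p = 3.08e-05), and C3ar1 (2.53 ± 0.24) and Itgb2 (2.61 ± 0.25). Of 20 reactive astrocyte genes 17 rose, or 19 adjusted over the list alone (median 1.72), among them Serpina3n (3.93 ± 0.35), Cd109 (2.18 ± 0.21) and Aspg (2.24 ± 0.24). Camera called all 3 lists (adjusted p = 4.34e-20, 1.16e-10 and 7.08e-13), with adjusted p = 0.37 for each with an estimated correlation. C4b, Lyz2, Serpina3n and the H2 genes have near-identical relatives, so the division of reads between copies is uncertain. Cst7 (ENSMUSG00000068129, chromosome 2, 150570415 to 150578944), Clec7a (ENSMUSG00000079293, chromosome 6, 129461591 to 129472779), Serpina3n (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329) and C4b (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882) were measured over their annotated exons.

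Other immune lists moved in the same direction in P. Of 17 homeostatic microglia genes 13 rose, the same number adjusted over the list alone (median 0.97), with Fcrls (3.24 ± 0.25) and Csf1r (1.53 ± 0.19). Of 8 genes of the NADPH oxidase, the enzyme of phagocytes that makes superoxide, 7 rose, or 8 adjusted over the list alone (median 1.29), with Cybb (2.43 ± 0.30) and Vav1 (1.32 ± 0.17). 14 of 17 antigen presentation genes rose, or 16 adjusted over the list alone (median 1.004), with Cd74 (2.65 ± 0.39), B2m (1.96 ± 0.30) and H2-K1 (1.64 ± 0.30). 19 of 23 cytokine and NF-kB genes rose, or 20 adjusted over the list alone (median 0.65), led by Ccl3 (3.34 ± 0.26), Ccl4 (2.58 ± 0.26) and Tlr2 (2.11 ± 0.21). For lysosome and autophagy genes the counts were 15 of 24, and 18 higher and 1 lower adjusted over the list alone (median 0.56), with Laptm5 (2.27 ± 0.24), Grn (2.27 ± 0.24) and Ctss (2.46 ± 0.28). Of 22 interferon response genes 6 rose, or 13 adjusted over the list alone (median 1.02), with Ifitm3 (1.74 ± 0.31) and Gbp2 (2.12 ± 0.44). Camera's adjusted p-values were 3.07e-07, 1.45e-06, 1.88e-07, 3.56e-09, 3.07e-07 and 1.46e-05 in that order. The first 5 lists had adjusted p = 0.37 with an estimated correlation, with adjusted p = 0.452 with an estimated correlation for the interferon list. The Gbp2 call was lost without P66.

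Genes of motor neurons fell. Of 19 motor neuron genes, 10 were lower in P, or 11 adjusted over the list alone (median -0.80, camera adjusted p = 4.08e-09, adjusted p = 0.37 with an estimated correlation). The score of that list was 4.79, 4.69 and 3.98 in H1, H2 and H4, and 3.42, 3.85 and 4.11 in P66, P67 and P74, so H4 lay below P74. Chodl, a marker of fast motor neurons (ENSMUSG00000022860, chromosome 16, 78930948 to 78951733), had 13.4 ± 5.59 FPKM in H and 2.05 ± 0.254 in P (-2.15 ± 0.28, adjusted p = 0.000939). Mmp9, a protease of vulnerable motor neurons, changed by -0.92 ± 0.15 (adjusted p = 0.00374), and the potassium channel gene Kcnj14 by -1.43 ± 0.26 (adjusted p = 0.00513). Pvalb, which encodes the calcium buffer parvalbumin, changed by -1.42 ± 0.27 (adjusted p = 0.00707) and Sncg, which encodes gamma-synuclein, by -0.90 ± 0.14 (adjusted p = 0.00233). Kcnj14 and Pvalb were named by size of change and are not on the motor neuron list, so the cells behind their changes are not known here. Pvalb was at -1.10 without H1 and -1.69 without H4. The skeletal muscle score also fell over H1, H2 and H4 (7.67, 4.31 and 1.79), and its part in the change of Pvalb was not tested. Of 20 general neuron and synapse genes 5 fell, or 10 adjusted over the list alone (median -0.37, camera adjusted p = 4.67e-07, adjusted p = 0.374 with an estimated correlation), with Stmn2 (-0.59 ± 0.13), Syp (-0.72 ± 0.18) and Snap25 (-0.51 ± 0.13). The median of the neuron list was -0.19 without P66. Of 16 axon injury genes 5 rose, or 7 with 1 lower adjusted over the list alone. They included Atf3, a transcription factor that injured neurons induce (2.42 ± 0.33, adjusted p = 0.00124), and Sprr1a (2.36 ± 0.17, adjusted p = 4.83e-05), but the list did not pass (median 0.29, camera adjusted p = 0.109). The caudal Hox score, the mean of 8 genes of Hox groups 10 to 13 that mark the caudal cord, was 0.36 in H4 and 0.97 in P66 and 1.47 to 2.65 in the other libraries of H and P. Calls of Stmn2, Syp and Snap25 were lost without H2, without P66 and with only the 2 groups in the fit.

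Energy and lipid genes fell. Of 32 nuclear genes of oxidative phosphorylation, the mitochondrial pathway that makes ATP, 17 fell, or 29 adjusted over the list alone (median -0.55, camera adjusted p = 3.16e-17), with Cycs (-0.56 ± 0.11), Ndufa9 (-0.64 ± 0.16) and Atp5k (-1.06 ± 0.27). Of 20 cholesterol synthesis genes 14 fell, or 15 adjusted over the list alone (median -0.57, camera adjusted p = 4.42e-15). Hmgcs1, an early enzyme of the pathway, had 67.4 ± 10.6 FPKM in H and 38 ± 2.98 in P (-0.80 ± 0.12, adjusted p = 0.00216), and Stard4 (-0.71 ± 0.10) and Fdft1 (-0.61 ± 0.10) also fell. Both lists had adjusted p = 0.37 with an estimated correlation. Of 12 mitochondrially encoded genes 1 fell, mt-Nd3 (-0.89 ± 0.26), or 0 adjusted over the list alone (median -0.35, camera adjusted p = 0.00206, adjusted p = 0.452 with an estimated correlation, call lost without H4, where the median was -0.17). Of 81 ribosomal protein genes 0 passed, over all genes or adjusted over the list alone (median -0.14, camera adjusted p = 0.000221, adjusted p = 0.62 with an estimated correlation). The ribosomal call was lost without H4, where the median was 0.03, and the median was -0.36 without H1. The calls of Ndufa9, Atp5k and mt-Nd3 were lost without H2, P66 or P67 and without the filter.

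Of the 18 superoxide and peroxide enzymes, named because of the activity of the carbon dots, 2 rose and 1 fell. Adjusted over the list alone, 2 rose and 2 fell (median -0.03, camera adjusted p = 0.337). Prdx6, a peroxiredoxin, rose by 1.45 ± 0.19 (adjusted p = 0.00114), Gpx8 by 1.14 ± 0.26 (adjusted p = 0.0144), and Prdx5 changed by -0.46 ± 0.14 (adjusted p = 0.0497). The Prdx5 call was lost in 7 of 15 settings and the Gpx8 call in 3, among them without H2 and without P66. Sod1, the cytosolic superoxide dismutase and an ALS gene (ENSMUSG00000022982, chromosome 16, 90220754 to 90226329), had 204 ± 49.3 FPKM in H and 151 ± 10.2 in P and did not pass (-0.41 ± 0.23, adjusted p = 0.231), nor did Sod2 (-0.37 ± 0.12, adjusted p = 0.0587). Sod2 passed in 6 of 15 settings (adjusted p from 0.00421 to 0.218), which were voom, median-ratio scaling, the fits without H4 and without P74, removal of length and GC trends, and the caudal covariate. Among 21 NRF2 targets, 5 rose, or 7 adjusted over the list alone, with Hmox1 (1.86 ± 0.25) and Ftl1 (1.76 ± 0.28), and the list did not pass (median 0.17, camera adjusted p = 0.0653). Of 18 metal handling genes 4 rose, or 5 adjusted over the list alone, among them the manganese and zinc transporter gene Slc39a14 (0.88 ± 0.18, adjusted p = 0.00877). That list had a median of 0.19 (camera adjusted p = 0.0497, adjusted p = 0.39 with an estimated correlation), and its call was lost without H1, without P66, with median-ratio scaling (adjusted p = 0.0611) and after removal of length and GC trends (adjusted p = 0.119).

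Lists of stress, cell death and oligodendrocyte lineage genes also passed camera. Of 19 p53 and cell death genes 11 rose, or 12 with 1 lower adjusted over the list alone (median 0.44, camera adjusted p = 0.000832, adjusted p = 0.37 with an estimated correlation), with Tnfrsf1a (1.72 ± 0.23). Of 14 immediate early genes 6 rose, or 8 adjusted over the list alone (median 0.44, camera adjusted p = 0.00745, adjusted p = 0.39 with an estimated correlation), with Fos (1.02 ± 0.17) and Junb (0.94 ± 0.15). Of 20 unfolded protein response genes 5 rose, or 7 adjusted over the list alone (median 0.33, camera adjusted p = 0.0122), and of 12 oligodendrocyte precursor genes 4 rose, or 8 adjusted over the list alone (median 0.32, camera adjusted p = 0.0356). Among 18 myelin genes Mog fell (-0.44 ± 0.11) and Opalin rose (0.61 ± 0.18), the same number adjusted over the list alone (median -0.14, camera adjusted p = 0.0133). These 3 lists had adjusted p = 0.39 with an estimated correlation, and their calls were lost without H4 (unfolded protein response and precursors), P74 (unfolded protein response), P66 (precursors) and P67 (myelin). Without H2 the unfolded protein response had a median of 0.53, and its call was also lost with the caudal covariate (0.28, adjusted p = 0.141). The Mog and Opalin calls were lost without H2, P66 or P67, and the Opalin call also with median-ratio scaling.

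Markers of tissue around the cord also differed between P and H. Of 12 Schwann cell and nerve root genes 4 rose, or 8 adjusted over the list alone (median 0.81, camera adjusted p = 0.00964, adjusted p = 0.411 with an estimated correlation, call lost without H4 and with the caudal covariate, where the median was 0.76 and the adjusted p 0.0677). The score of that list was 3.70, 3.22 and 2.88 in H1, H2 and H4, and 4.04, 4.31 and 4.08 in P66, P67 and P74. Of 15 meningeal and fibroblast genes 3 rose, or 4 adjusted over the list alone (median 0.91, camera adjusted p = 0.00206, adjusted p = 0.452 with an estimated correlation), with Fmod (3.06 ± 0.51), Ogn (2.69 ± 0.51) and Thbs2 (1.82 ± 0.24). The meningeal median was 0.49 without P66. Of 9 erythroid genes 3 fell, or 5 adjusted over the list alone (median -1.53, camera adjusted p = 3.90e-05, adjusted p = 0.374 with an estimated correlation). They were the haemoglobin genes Hba-a1 (-2.72 ± 0.61), Hbb-bt (-2.52 ± 0.62) and Hbb-bs (-2.36 ± 0.62), whose near-identical copies make single values uncertain and whose calls were lost in 2, 3 and 6 of 15 settings, for each gene also without P66. Of 9 skeletal muscle genes 0 passed, over all genes or adjusted over the list alone (median -2.55, camera adjusted p = 0.000221, adjusted p = 0.39 with an estimated correlation). The muscle median was -1.02 without H1 and -4.06 without H4, and the score of the list was 1.79 in H4, below the 4.004 of P74. Acta1 of skeletal muscle had 796 FPKM in H1, 46.9 in H2, 6.25 in H4 and at most 35.3 elsewhere.

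In P against H camera called 16 lists higher and 9 lower, while fry called 22 higher and 3 lower. Both called 19 lists in the same direction, so most of camera's lower calls were not shared by fry. The other lists did not pass camera in P against H. Their medians were 0.19 for astrocyte identity, where 6 of 15 genes rose, and 6 adjusted over the list alone, 0.31 for border and blood macrophages, 0.34 for pericytes, 0.20 for T and NK cells, 0.08 for B cells and 0.16 for neutrophils. They were 0.16 for the circadian clock, -0.17 for the glucocorticoid response, -0.07 for hypoxia and glycolysis, -0.04 for heat shock and 0.03 for ALS-linked genes. They were 0.00 for endothelial cells, 0.14 for ependymal cells, 0.01 for sensory ganglia and 0.24 for sex-linked genes. Ang, an ALS-linked ribonuclease gene, rose (1.13 ± 0.18), and Kif5a, an ALS-linked kinesin of axonal transport, fell (-0.64 ± 0.14, adjusted p = 0.0119), a call lost with only the 2 groups in the fit (adjusted p from 0.00323 to 0.0512 over the settings).

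In total limma called 2807 genes in P against H, 2216 higher and 591 lower, of which 419 and 33 changed at least 2-fold. At an unadjusted p under 0.05 there were 5924, against 906 from chance alone. The number was 933 without P66, 1122 without H2, 1272 without P67, 1440 without the filter and 1471 with only the 2 groups in the fit. The share of higher genes was 78.9%, against 53.2% with median-ratio scaling, which lowered the log2 changes by a median of 0.0906 over genes, and 57.3% after removal of length and GC trends.

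**Figure D1:**
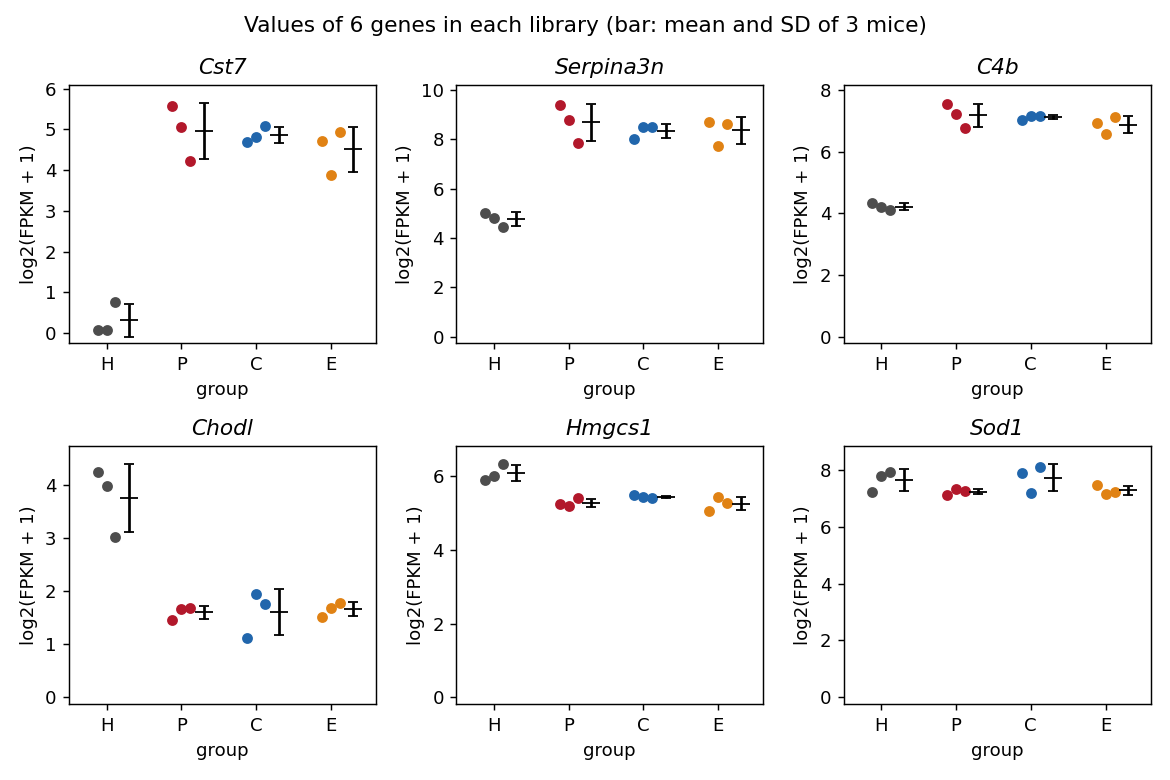
Values of 6 genes, as log2(FPKM + 1), in each library of healthy mice (H) and of ALS model mice given saline (P), carbon dots (C) or edaravone (E), with bars for the mean and SD of 3 mice. Cst7, Serpina3n and C4b lie higher and Chodl and Hmgcs1 lower in all 9 ALS model libraries than in the 3 healthy ones, while Sod1 overlaps (adjusted p = 0.231 for P against H).

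The comparison of C with P asks what the carbon dots change in the ALS model. 1 gene passed, Gm10479, a gene model annotated as an intergenic noncoding RNA (ENSMUSG00000073184, chromosome 12, 19292813 to 19301264), which was named after its value was seen. It had 0.303 ± 0.278 FPKM in P, 3.39 ± 1.09 in C, 1.97 ± 0.409 in H and 1.59 ± 0.252 in E, and was higher in C by 1.75 ± 0.19 (adjusted p = 0.0243) and it had changed by -1.20 ± 0.19 from H to P (adjusted p = 0.00306). Its call was lost in 9 of 15 settings (adjusted p from 0.00626 to 0.457), among them limma-voom and leaving out P67, P74, C79, C84 or C85. Of the genes named as not passing, those with higher values in C were BC051226 (0.80 ± 0.11), Tppp3 (0.57 ± 0.10), Stra6 (0.56 ± 0.10), Higd1b (0.77 ± 0.14) and Sstr3 (0.57 ± 0.11), with adjusted p = 0.0717 for BC051226 and 0.395 for Tppp3. BC051226 passed in 2 of 15 settings, median-ratio scaling and the FPKM filter (adjusted p from 0.0487 to 0.461). Tppp3 encodes a tubulin-binding protein, and it had 82.1 ± 8.3 FPKM in P and 122 ± 9.37 in C. Those with lower values were Styx (-0.36 ± 0.08), Ccnjl (-0.31 ± 0.07), Gtpbp8 (-0.27 ± 0.07), Srsf4 (-0.29 ± 0.07) and Desi2 (-0.35 ± 0.09).

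4 lists passed camera in C against P, all with higher values in C. For 81 ribosomal protein genes the median was 0.53, and 77 were positive (camera adjusted p = 1.66e-28). Of 32 nuclear oxidative phosphorylation genes 30 were positive (median 0.39, camera adjusted p = 1.50e-12), and 11 passed adjusted over the list alone. Of 18 superoxide and peroxide enzymes 15 were positive (median 0.27, camera adjusted p = 5.11e-05), and of 12 endothelial genes 12 (median 0.16, camera adjusted p = 0.00393). 0 members of the 4 lists passed over all genes, and 0 adjusted over the list alone in 3 of them. Each list had adjusted p = 0.81 with an estimated correlation, and fry gave adjusted p of 0.4996, 0.489, 0.409 and 0.489. The endothelial call was lost without P74, where the enzyme list had a median of 0.16. The enzymes with the largest differences were Sod1 (0.49 ± 0.23), Txn1 (0.48 ± 0.16), Gpx4 (0.43 ± 0.12), Prdx5 (0.43 ± 0.14) and Gpx1 (0.40 ± 0.14), with adjusted p = 0.508 for Sod1, which ran from 0.31 without C85 to 0.76 without C84. Txn1 (0.36 to 0.64), Gpx4 (0.35 to 0.56) and Prdx5 (0.34 to 0.59) were also lowest without C85 and highest without C84. Gpx1 ran from 0.27 without P74 to 0.47 without P66. The enzyme score was 4.81, 4.69 and 4.88 in C79, C84 and C85, and 4.63, 4.59 and 4.48 in P66, P67 and P74. The ribosomal score was 5.78 in C79, 5.91 in C85 and 5.22 in C84, against 5.03 to 5.20 in P. C79 and C85 also stood apart in the slope of log2 value on exon length over other genes, at -0.0477 and -0.0543 against 0.00948 in C84 and 0.00842 to 0.0235 in P.

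**Figure D2:**
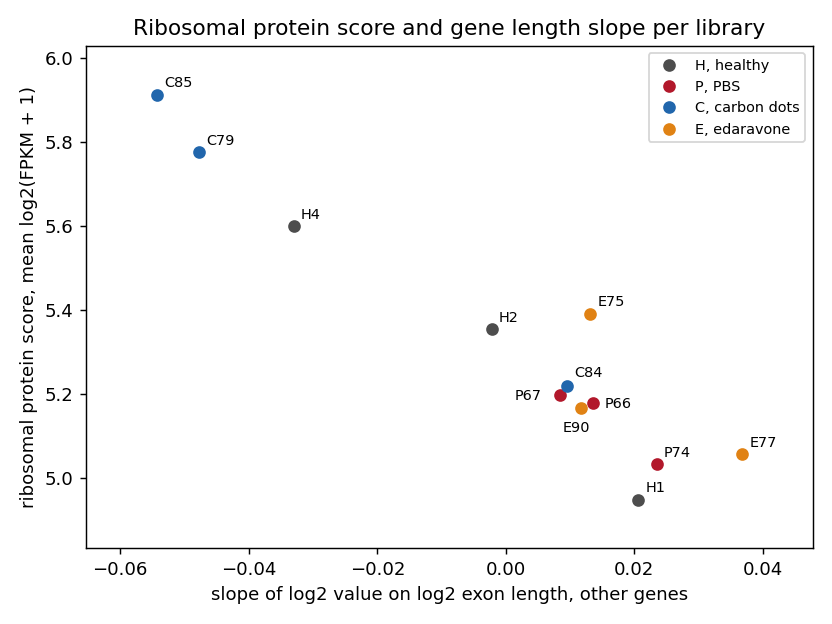
Ribosomal protein score of each library (mean log2(FPKM + 1)) against the slope of log2 value on log2 exon length over the other genes, 1 point per mouse, coloured by group. C79 and C85 lie at 5.78 and 5.91 with slopes of -0.0477 and -0.0543, while C84 (5.22) lies among the P and E libraries.

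Other lists did not pass between C and P, with ranges here from fits without single libraries. Disease-associated microglia had a median of -0.08 (-0.32 to 0.22, camera adjusted p = 0.83), reactive astrocytes of -0.13 (-0.38 to 0.12, 0.552), motor neurons of 0.04 (-0.13 to 0.19, 0.795) and myelin of 0.09 (0.0592). Skeletal muscle genes had -1.35 (-1.99 to -0.33, 0.085). Without P74 the lists of microglia (-0.32), astrocytes (-0.38) and motor neurons (0.19) passed, without P66 those of microglia (0.22) and muscle (-1.99), and muscle also without P67 (-1.85). The caudal Hox score was 1.51, 0.61 and 1.41 in C79, C84 and C85, against 0.97, 2.19 and 2.65 in P66, P67 and P74. With that score as a covariate, an alternative added after seeing the data, 11 lists passed. Among them were disease-associated microglia (-0.21, adjusted p = 0.0159), motor neurons (0.29, adjusted p = 1.86e-06) and, narrowly, myelin (0.11, adjusted p = 0.04998). No estimated correlation was run with the covariate. Beside the 1 call of limma, voom called 0 genes, and 1802 had an unadjusted p under 0.05. The count was 2 without P66 and 0 without each other library, 2 with median-ratio scaling, 5 without the filter, 4 with an FPKM filter, and 0 with a pseudocount of 0.1 or the caudal covariate.

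**Figure D3:**
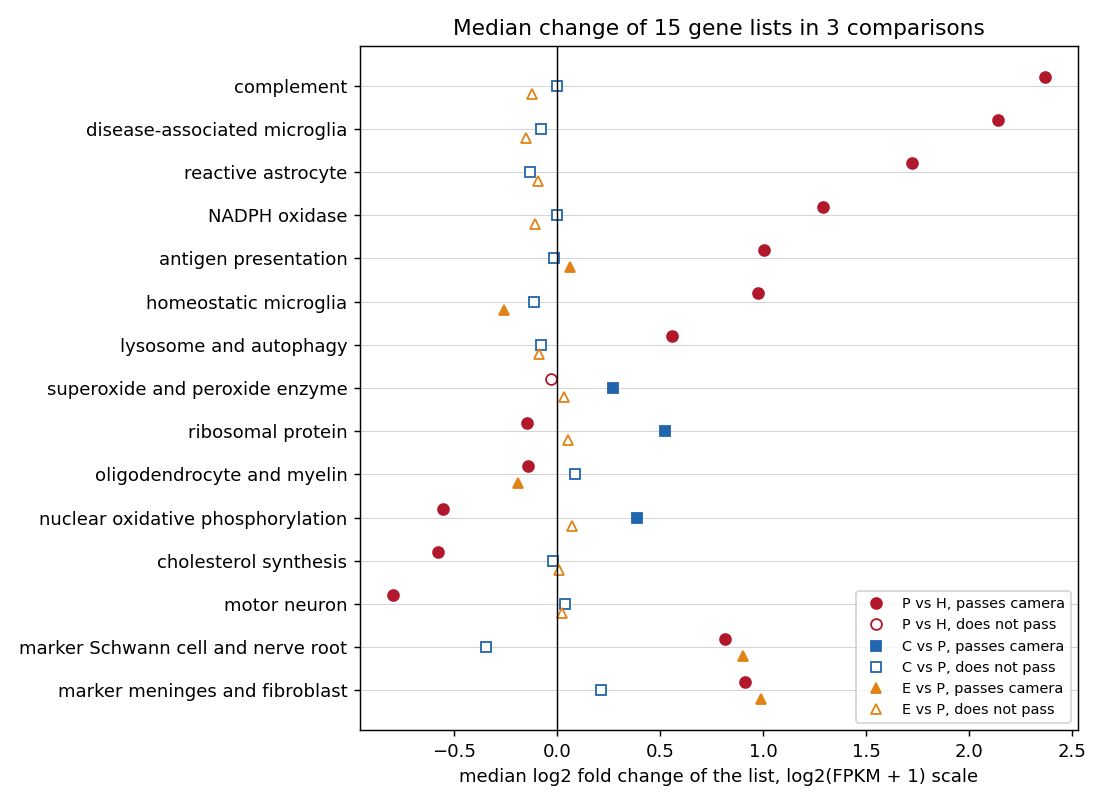
Median log2 fold change, on the log2(FPKM + 1) scale, of 15 gene lists in P against H, C against P and E against P (3 mice per group), with filled symbols for lists that pass camera. Complement (2.37) and disease-associated microglia (2.14) lie far above 0 in P against H and near 0 between treated and saline mice.

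The comparison of E with P asks the same of edaravone. Limma called 0 of 18119 genes (smallest adjusted p = 0.0913), voom called 0, and 889 had an unadjusted p under 0.05 against 906 from chance alone. The genes named as not passing with higher values in E were led by Lcn2, an iron-binding acute-phase protein (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), with 2.23 ± 0.747 FPKM in P and 11.7 ± 4.3 in E (1.94 ± 0.26, adjusted p = 0.0913). The cell death regulator gene Bok (0.80 ± 0.11), the vitamin A transporter gene Stra6 (0.67 ± 0.10), the laminin gene Lamb1 (1.14 ± 0.18) and the sodium channel gene Scn7a of Schwann cells (0.95 ± 0.16, adjusted p = 0.187) followed. Lcn2 passed without E75 (adjusted p from 0.0118 to 0.532 over the settings), Lamb1 without E77 (from 0.0399) and Bok after removal of length and GC trends (from 0.0210). Those with lower values were Tmprss5 (-0.54 ± 0.13), Car2 (-0.49 ± 0.10), Sox2ot (-0.47 ± 0.10), Ccdc191 (-0.40 ± 0.10) and Pls1 (-0.38 ± 0.09).

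12 lists passed camera in E against P, 8 higher and 4 lower, while 0 of their members passed over all genes. Schwann cell and nerve root genes had the smallest adjusted p (median 0.90, 4.32e-10, with 8 of 12 adjusted over the list alone). Immediate early genes followed (median 0.35, 5.02e-09, 6 of 14 adjusted over the list alone), and then meningeal genes (median 0.99, 3.01e-08, 6 of 15 adjusted over the list alone) and glucocorticoid response genes (median 0.30, 2.32e-06, 2 of 12 adjusted over the list alone). Border and blood macrophage (median 0.28, 1 of 9 adjusted over the list alone), neuron (0.18), endothelial (0.26) and antigen presentation genes (0.07) also passed. The lists with lower values were myelin (median -0.19, 1.23e-07, 1 of 18 positive), homeostatic microglia (-0.26, 3.16e-07, 0 of 17 positive), oligodendrocyte precursors (-0.12, 0.0123) and mitochondrially encoded genes (-0.15, 0.015). Medians of all but the Schwann cell list moved by over 1.5 times without a single library. Without E75 they were -0.08 for myelin, 0.66 for meningeal and 0.60 for glucocorticoid genes, and without E90 0.14 for glucocorticoid and 0.15 for macrophage genes. They were -0.10 for homeostatic microglia without P66, -0.43 for homeostatic microglia, 0.65 for meningeal and 0.14 for endothelial genes without P74, and 0.21 for immediate early genes without E77. For the lists given without such a count, 0 members passed adjusted over the list alone. Schwann cell, immediate early and myelin genes had adjusted p = 0.223 with an estimated correlation. The values with an estimated correlation were adjusted p = 0.432 for meningeal, glucocorticoid, endothelial, homeostatic microglia and precursor genes, 0.466 for macrophages and 0.925 for the rest. Fry called 0 lists.

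The calls of macrophage (0.20) and endothelial genes were lost without P74, of neuron genes without P66 (0.02) or E77 (0.16), of precursors without P66 (-0.071) or E75 (-0.11), and of mitochondrially encoded genes without P66 (-0.027) or E75 (-0.078). Neuron genes had 0.10 without E75, 0.28 without E90 and 0.28 without P74, and precursors -0.19 without P74. The antigen presentation call was lost without P74 (-0.037), E75 (-0.00062) or E90 (-0.0073), and the median was 0.37 without E77, 0.30 without P66 and 0.11 without P67. The call was also lost after removal of length and GC trends (adjusted p = 0.0728). Disease-associated microglia (-0.15, camera adjusted p = 0.0761), reactive astrocyte (-0.09, camera adjusted p = 0.755), motor neuron (0.03), ribosomal (0.06) and oxidative phosphorylation genes (0.07) did not pass. Without single libraries the microglia median ran from -0.39 to 0.06, passing without P74, E75 (-0.21) or E90 (-0.24), and that of motor neurons from -0.15 to 0.20, passing without P66 or P74, the lowest and highest. The astrocyte list passed in both directions, at 0.20 without P66, 0.17 without E77 and -0.42 without P74. With the caudal covariate 16 lists passed, among them motor neurons (-0.20, adjusted p = 1.40e-05), and the calls of neuron (0.096, adjusted p = 0.264) and mitochondrially encoded genes (-0.077, adjusted p = 0.134) were lost, while disease-associated microglia had 0.0086 (adjusted p = 0.840). Homeostatic microglia kept their call with a smaller change (-0.11, adjusted p = 0.00408), and antigen presentation genes had a larger one (0.23, adjusted p = 0.000242). The Schwann cell score was 5.08, 4.65 and 5.40 in E75, E77 and E90, and the caudal Hox score was 2.27, 2.67 and 2.79 in the same libraries. The count of called genes was 1 without E75, 2 without E77, 1 without E90, 3 without the filter, and 1 with an FPKM filter or after removal of length and GC trends.

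The treatments were also compared directly. Between C and E, 31 genes passed, 22 lower and 9 higher in C, while without C84 12 were lower and 33 higher, and 15 of these 45 were among the 31. Those named here were chosen after their values were seen. The lower genes included the sodium channel gene Scn7a of Schwann cells, with 1.19 ± 0.422 FPKM in C and 5.1 ± 1.26 in E (-1.48 ± 0.16, adjusted p = 0.0184, ENSMUSG00000034810, chromosome 2, 66673425 to 66784914), the peripheral myelin gene Pmp22, with 73.3 ± 28.4 and 277 ± 103 (-1.91 ± 0.32, adjusted p = 0.0485), and Dhh (-2.14 ± 0.33), Gldn (-1.90 ± 0.29), Col28a1 (-1.76 ± 0.27), Drp2 (-1.21 ± 0.18), Matn2 (-1.12 ± 0.19) and Sbspon (-0.94 ± 0.15). The chemokine gene Ccl11 (-2.56 ± 0.39, adjusted p = 0.0277), Lcn2 (-1.83 ± 0.26, adjusted p = 0.0253) and Sostdc1 (-1.86 ± 0.23), Steap4 (-1.89 ± 0.28), Angptl4 (-1.60 ± 0.22), Lamb1 (-1.33 ± 0.18), Cd5l (-1.30 ± 0.18), Arhgap19 (-1.41 ± 0.21), Chrdl1 (-0.80 ± 0.13) and Prrg3 (-0.73 ± 0.11) were also lower, as were the gene models Gm45564 (-1.71 ± 0.27) and Gm13111 (-0.75 ± 0.10). Hoxc12, a Hox gene of the caudal cord (ENSMUSG00000050328, chromosome 15, 102936757 to 102938609), was listed at 0 in all 3 C libraries and at 3.38, 3.94 and 3.06 FPKM in E75, E77 and E90 (adjusted p = 0.0277). Higher in C were Tppp3, with 122 ± 9.37 FPKM in C and 77.9 ± 3.6 in E (0.64 ± 0.10, adjusted p = 0.033), Tmem125 (0.62 ± 0.07), Nkx2-9 (0.97 ± 0.16), Tmprss5 (0.89 ± 0.13), Aven (0.63 ± 0.10) and Rab37 (0.63 ± 0.09) and the gene models Gm32122 (1.04 ± 0.15) and Gm31166 (0.58 ± 0.10).

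12 lists passed camera between C and E. Lower in C were Schwann cell genes (median -1.34, camera adjusted p = 1.20e-08), of which 3 of 12 fell, or 9 with 2 higher adjusted over the list alone. That list had adjusted p = 0.467 with an estimated correlation. Immediate early (-0.41, 2.75e-06, 7 of 14 lower adjusted over the list alone), glucocorticoid (-0.37, 2.96e-05, 4 of 12), interferon (-0.49, 0.00228, 0 of 22), neuron (-0.15, 0.023, 2 of 20) and meningeal genes (-0.11, 0.038, 6 of 15) followed, with adjusted p = 0.55, 0.647, 0.997, 0.997 and 0.997 with an estimated correlation. Higher in C were ribosomal protein (median 0.48, 2.37e-22, 0 of 81 adjusted over the list alone), myelin (0.30, 1.12e-09, 7 of 18, all 18 positive), oxidative phosphorylation (0.30, 1.47e-08, 0 of 32), superoxide and peroxide enzyme (0.22, 0.00027, 2 of 18), homeostatic microglia (0.16, 0.00228, 0 of 17) and mitochondrially encoded genes (0.24, 0.00264, 0 of 12). In that order they had adjusted p = 0.914, 0.29, 0.914, 0.55, 0.997 and 0.997 with an estimated correlation. Fry called myelin and Schwann cell genes (adjusted p = 0.0412 for each). Calls were lost without C84 for interferon, homeostatic microglia and neuron genes, without C79 for mitochondrially encoded and meningeal genes, without C85 for neuron genes, without E75 for mitochondrially encoded, neuron and meningeal genes, without E77 for homeostatic microglia and neuron genes, and without E90 for interferon (-0.054) and meningeal genes (-0.053). Meningeal medians were 0.02 without C79, -0.36 without C84, -0.041 without E75 and -0.46 without E77. Without C84 they were 0.40 for mitochondrially encoded and 0.47 for oxidative phosphorylation genes, and without C79 0.15 for mitochondrially encoded genes and 0.25 for homeostatic microglia. Without E75 they were 0.19 for myelin and -0.58 for glucocorticoid genes, and without E90 -0.21 for glucocorticoid and -0.29 for neuron genes. Without E77 they were 0.14 for the enzymes, -0.27 for immediate early genes, -0.91 for interferon genes and 0.038 for homeostatic microglia. With the caudal covariate calls were lost for homeostatic microglia (-0.22, adjusted p = 0.102) and neuron genes (0.04, adjusted p = 0.475), both with turned sign, and for mitochondrially encoded genes (0.037, adjusted p = 0.240), and after removal of length and GC trends for neuron genes (adjusted p = 0.0640). That covariate left 18 lists called. Newly among them were motor neuron (0.49, camera adjusted p = 8.49e-12), reactive astrocyte (-0.44, 0.000237) and disease-associated microglia genes (-0.28, 0.0153). Without the covariate these 3 medians were 0.00077, -0.08 and 0.14. The meningeal median with the covariate was -0.56 (0.00164). Caudal scores of C (0.61 to 1.51) and E (2.27 to 2.79) do not overlap. All values adjusted for that score therefore rest on its slope within groups, and no conclusion is drawn from them.

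The caudal Hox and Schwann cell scores moved with these genes. The Schwann cell score was 3.604, 3.67 and 4.19 in C79, C84 and C85 and 5.08, 4.65 and 5.40 in E75, E77 and E90. Hoxd10, another caudal Hox gene, was listed at 0 in C84 and had 24.0 FPKM in E90. With the caudal score as a covariate, or with the Schwann cell score, limma called 0 genes between C and E, with 1599 and 1475 at an unadjusted p under 0.05. The caudal covariate left the median size of the 31 genes at 1.28, from 1.30, with all 31 signs kept, and their calls ended as the median standard error rose from 0.183 to 0.253. The Schwann cell list had a median of -1.06 with it (camera adjusted p = 4.44e-05), from -1.34. The Schwann cell score removes differences of Schwann cell genes by construction. An unadjusted p under 0.05 was given to 1991 genes without a covariate, and voom called 27. The count was 0 without C79, 1 without C85, 9 without E90, 15 without E75, 45 without C84 and 56 without E77, and it was 4 without the filter or with only the 2 groups in the fit, and 17 with a pseudocount of 0.1.

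**Figure D4:**
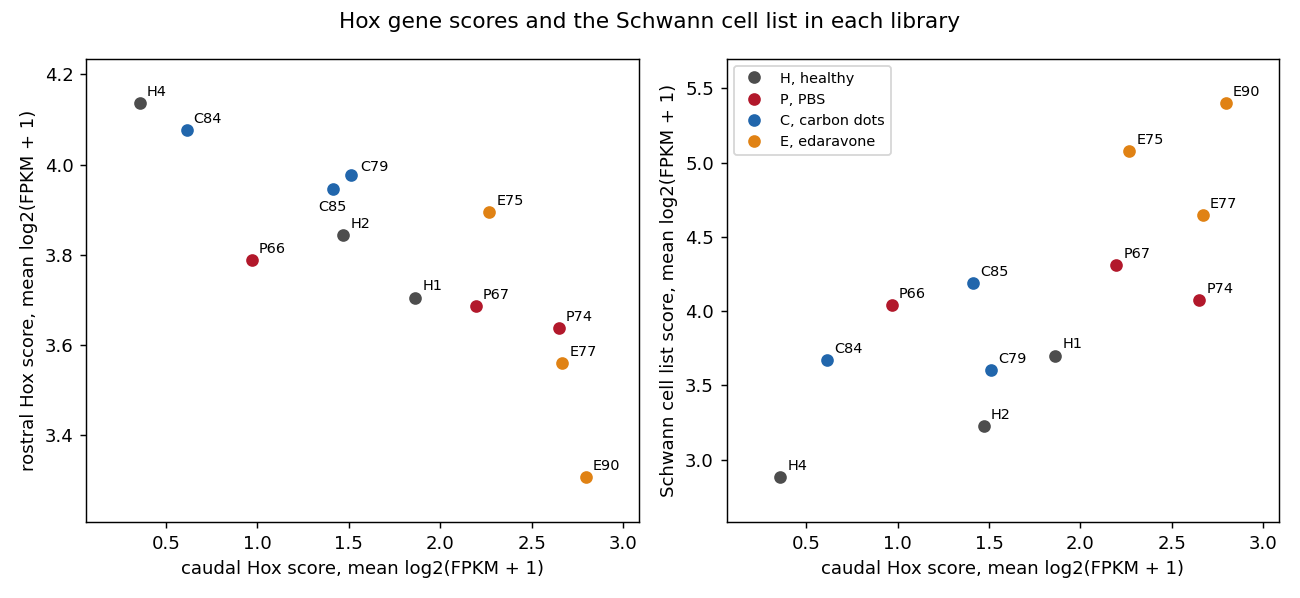
Caudal Hox score of each library (mean log2(FPKM + 1) of 8 genes) against the rostral Hox score (left) and the Schwann cell list score (right), 1 point per mouse. The 3 E libraries lie at 2.27 to 2.79 on the caudal score and the 3 C libraries at 0.61 to 1.51, with H4 lowest at 0.36.

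The treated groups were also set against healthy mice. In C, 22 of 28 disease-associated microglia genes rose, or 26 adjusted over the list alone (median 2.05), 11 of 14 complement genes, or 13 adjusted over the list alone (2.36), and 17 of 20 reactive astrocyte genes, or 18 adjusted over the list alone (1.46). 14 of 20 cholesterol synthesis genes fell, or 17 adjusted over the list alone (-0.53), as did 4 of 19 motor neuron genes, or 15 with 1 higher adjusted over the list alone (-0.73, camera adjusted p = 7.99e-11). These lists had adjusted p = 0.264 with an estimated correlation. Oxidative phosphorylation genes had a median of -0.15 with 1 of 32 lower, or 0 adjusted over the list alone (camera adjusted p = 2.89e-06, adjusted p = 0.399 with an estimated correlation), and without C84 the call was lost and the median was 0.01 (-0.25 without C79, -0.24 without C85). Meningeal genes were higher in 7 of 15, or 13 adjusted over the list alone (1.31, adjusted p = 0.298 with an estimated correlation). Limma called 1505 genes, 1313 higher and 192 lower, with 4675 at an unadjusted p under 0.05. The number was 567 without H2, 599 without C85, 754 without C84, 891 without H1 and 740 without the filter, and the share of higher genes was 87.2%, against 66.9% with median-ratio scaling and 66.7% after removal of length and GC trends.

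In E, 24 of 28 disease-associated microglia genes rose, or 25 adjusted over the list alone (median 1.94), 13 of 14 complement genes, also 13 adjusted over the list alone (2.01), and 19 of 20 reactive astrocyte genes, or 20 adjusted over the list alone (1.74). 9 of 19 motor neuron genes fell, or 10 adjusted over the list alone (-0.74), as did 13 of 20 cholesterol synthesis genes, or 17 adjusted over the list alone (-0.58), 3 of 32 oxidative phosphorylation genes, or 22 adjusted over the list alone (-0.51), and 4 of 18 myelin genes, or 9 adjusted over the list alone (-0.29, camera adjusted p = 1.08e-07). Schwann cell genes rose in 10 of 12, or 10 with 1 lower adjusted over the list alone (1.72, camera adjusted p = 6.27e-07), meningeal genes in 12 of 15, or 13 adjusted over the list alone (1.75), and immediate early genes in 10 of 14, or 11 adjusted over the list alone (0.84). All of these lists had adjusted p = 0.272 with an estimated correlation. Limma called 2392 genes, 2002 higher and 390 lower, with 5380 at an unadjusted p under 0.05. The number was 1159 without E90, 1167 without H2 and 1467 without the filter, and the share of higher genes was 83.7%, against 58.4% with median-ratio scaling and 61.6% after removal of length and GC trends.

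Of the genes called in P against H, 1070 of the higher and 124 of the lower were called in the same direction in C against H, and 1428 and 268 in E against H. Independent lists would share 161 and 6.26 for C and 245 and 12.7 for E, and simulated groups without effects shared at most 0.05 on average over 20 simulations, a value near 0 because such groups give almost no calls, so it does not measure what shared controls add. The 3 healthy libraries cannot be divided into parts of at least 2, so part of the excess can come from the shared controls.

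Whether treatment moved disease changes back was measured over the 2807 genes of P against H. Of these, 1 was called in the opposite direction in C against P (Gm10479) and 0 in E against P, by limma at an adjusted p under 0.05. Voom called 0 genes in either comparison. Signs were opposite for 2302 genes (82.0%) in C and 2088 (74.4%) in E. P libraries that are shared between the comparisons raise such shares. In 20 simulations that kept the disease difference and gave P, C and E equal means, added after these values were seen, the shares were 65.1 ± 0.847% and 65.0 ± 0.682% (SD) over the genes called there. These simulations draw genes independently, so their SD leaves out differences between mice that many genes share. The correlations of the changes across genes were -0.351 and -0.193. In simulations without group effects they were -0.503 and -0.499. Those hold no disease difference, and the shared P mean alone fixes such values, so no conclusion is drawn from this contrast. The covariance across genes of the changes was -0.0286 for C, against -0.0173 ± 0.00135 (SD) in 100 simulations without effects. For E it was -0.0135, against -0.0171 ± 0.00108 (SD). In the 20 simulations that kept the disease difference it was -0.0158 ± 0.00133 (SD) for C and -0.0157 ± 0.00113 (SD) for E. The covariance of C was thus more negative than in either set of simulations and that of E less. These simulations draw genes independently as well, so distances in their SD do not measure a treatment effect. C against P and E against P had a covariance of 0.0109, against 0.0173 simulated. With each P library held out of the disease estimate in turn, the mean slope was -0.11 ± 0.27 (SD, n = 3) for C and -0.05 ± 0.26 (SD, n = 3) for E. The 3 slopes share the H libraries and the same C or E mean, and were taken over different genes. Their SD is therefore not the error of a treatment effect, and the slopes do not test whether such an effect differs from 0. The slopes were -0.37, -0.12 and 0.17 for C with P66, P67 and P74 held out, and -0.30, -0.07 and 0.21 for E.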

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

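In the weighing below, the tests of the length slope, of both treatments, of level as the cause of Schwann cell and motor neuron differences and of a smaller share of neurons were chosen after the result was seen. For the tests on splits, on trend removal, on nerve root tissue and on a more caudal piece, the predictions were written before their results. Trend removal itself was added after the data had been seen, and the caudal Hox genes were listed after Hoxc12 had been noticed.

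The direct comparison of groups C and E stood out because genes passed in it, while limma called 1 gene in C against P and 0 in E against P. A difference between these groups need not come from treatment, because their caudal Hox and Schwann cell scores differed as well. The count of called genes was 0 without C79 and 1 without C85. limma called 31 genes between C and E, 9 higher and 22 lower in C (33 and 12 without C84). Other splits of the same 6 libraries into 3 and 3 called at most 0 genes, and 1 of the 10 splits, the real one, called as many. Of the 10 splits per comparison, 1 also reached the real count of 2807 in P against H (highest other 0), of 1 in C against P (highest other 0), of 1505 in C against H (highest other 2) and of 2392 in E against H (highest other 124, with H1, H2 and E90 on one side). In E against P, where limma called 0 genes (889 at an unadjusted p under 0.05, voom 0), all 10 splits gave 0. 10 splits are too few for a share under 0.05.

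The lists of ribosomal protein and oxidative phosphorylation genes had higher values in C than in P, by medians of 0.53 and 0.39. No member of either list passed over all genes. Both camera calls were lost with an estimated correlation (adjusted p = 0.81) and with fry. Removal of each library's trend on exon length and GC content left ribosomal medians of 0.450 (0.309 to 0.668 without single libraries), which argues against these trends as the whole cause. Within groups, the ribosomal score fell with the length slope of the other genes (r = -0.958, permutation p = 0.00219, adjusted 0.00657 over 6 relations, rho = -0.909, permutation p = 0.0048, r = -0.901 without the 2 farthest libraries), consistent with a property of single libraries, such as RNA quality or library preparation, that also varies within groups. Carbon dot treatment stays open, since C84 lies only 0.0197 above the highest P library in the ribosomal score and, for oxidative phosphorylation, lies at 5.46 below the 5.53 of P74, so both differences rest mainly on C79 and C85. Which of these accounts for the difference was not resolved with 3 libraries per group. The enzyme list, also higher in C than in P, was not put to the test of the length slope.

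The lists of Schwann cell and meningeal genes had higher values in E than in P, and that of Schwann cell genes higher values in E than in C. No member passed over all genes in E against P. With an estimated correlation no list passed in E against P or C against E (smallest adjusted p 0.223 and 0.290). Fry called the Schwann cell list in C against E only. Apart from Hoxc12, Hox genes of groups 11 to 13 had a median difference of 1.03 between E and C, which met the criterion written beforehand for a more caudal piece in E. With the caudal Hox score as covariate, Schwann cell medians stayed at -1.06 in C against E (from -1.34, -1.29 to -0.77 without single libraries). In E against P they stayed at 0.82 (from 0.90, 0.61 to 0.93), and meningeal ones at 1.17 (0.82 to 1.41). Caudal scores of C (0.61 to 1.51) and E (2.27 to 2.79) do not overlap, so the adjustment between them rests on the slope within groups and does not decide. P67 and P74, at 2.19 and 2.65, lay near or within the range of E. The E against P medians therefore argue against level as the whole cause there. More nerve root and meningeal tissue stays open, because the Schwann cell and meninges scores had an r within groups of 0.599 (permutation p = 0.0789, adjusted 0.118 over 6 relations, rho = 0.469, permutation p = 0.160, r = 0.576 without the 2 farthest). An effect of edaravone also stays open, since the lowest E library lay 0.335 above the highest other library in the Schwann cell score. More nerve root tissue and edaravone cannot be told apart here, because each would follow the group.

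Motor neuron genes were lower in P than in H, by a median of -0.80. Adding the caudal Hox score as a covariate gave -1.005 (-1.04 to -0.94 without single libraries), which argues against rostrocaudal level as the cause of the fall. A smaller share of all neurons stays open, because the general neuron list had a median of -0.369 with leave-one-out values of -0.48 to -0.19, against -0.95 to -0.56 for motor neuron genes. The ALS model itself, the difference that the design names, also stays open and may act through loss of these neurons or lower expression in them, which RNA of whole tissue does not separate.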

How the results depend on the processing

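The pseudocount, the FPKM filter, the removal of length and GC trends, both covariates, the slope through 0 and the list tests with other scaling were chosen as alternatives after seeing the data, and the others before. The alternatives with DESeq2 and edgeR were not run because the values are FPKM, and the sex covariate was not run because its condition was not met. No paired analysis was possible because no mouse number is shared between groups. Using library size only changed nothing, since it is the scaling of the values. Over 200 gene results, 1821 planned and 717 added alternatives kept direction and side of the threshold, 346 and 97 lost the call, 10 and 6 gained one, and 23 and 10 changed sign. Of 112 genes named in P against H 97 were called, and 65 lost the call in no setting (15 each, or 14 for Cd8a), while all 31 genes of C against E lost it in 1 or more of 16 (limma). The depth of 16.8 to 19.8 M recovered reads leaves genes under 10 reads untested.

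Counts of called genes in the order P against H, C against P, E against P, C against E, C against H and E against H were 2807, 1, 0, 31, 1505 and 2392. They were 3070, 0, 0, 27, 1698 and 2671 with voom, 2626, 2, 0, 34, 1391 and 2205 with median-ratio scaling, 1440, 5, 3, 4, 740 and 1467 without the filter (32885 genes tested), and 1471, 1, 0, 4, 1585 and 1750 with only the 2 groups, where the gene of C against P was another. They were 3077, 0, 0, 17, 1835 and 2705 with a pseudocount of 0.1, 2658, 4, 1, 25, 1407 and 2212 with the FPKM filter, 2878, 1, 1, 41, 1523 and 2347 without length and GC trends, and 3991, 0, 0, 0, 1935 and 3031 with the caudal covariate. The nerve root covariate left 0 genes in C against E. Without single libraries the counts ran from 933 (P66) to 3535 (P74), 0 to 2, 0 to 2, 0 (C79) to 56 (E77), 567 (H2) to 1915 (H4) and 1159 (E90) to 2230. The causes were not tested. The fit without the filter tested more genes, the smaller fits held fewer libraries, and the caudal covariate raised the standard errors of the 31 genes of C against E. Fewer libraries did not always give fewer calls, since P against H had 3535 without P74.

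Camera called 25, 4, 12, 12, 25 and 25 lists. An estimated correlation left 0 in all 6 comparisons (smallest adjusted p 0.370, 0.810, 0.223, 0.290, 0.264 and 0.272). Fry called 25, 0, 0, 2, 26 and 28, and the caudal covariate gave 24, 11, 16, 18, 25 and 26. The lists of fry were not all those of camera. In P against H, 19 were called by both in the same direction, in C against H 19 and in E against H 21. Fry called 3, 3 and 5 lists lower there, against 9, 7 and 9 by camera. Without single libraries the numbers ran from 23 to 28, 5 to 15, 10 to 21, 9 to 15, 23 to 27 and 24 to 27, with 15 without P74, 12 without P66 and 7 without C79 in C against P, and 21 without E90 and 20 without P74 in E against P. The reversal slope with P74 held out was 0.17 for C and 0.21 for E, against means of -0.11 and -0.05, -0.05 and -0.06 over the 200 genes of smallest p, and -0.10 and -0.07 through 0.

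Among named genes, signs changed only for enzymes that passed in neither setting. In P against H, Gpx3 was -0.056 with median-ratio scaling and -0.024 with the caudal covariate, which gave 0.066 for Prdx4 and 0.052 for Txnrd2. In C against P, removal of trends gave 0.056 for Sod2 and -0.029 for Prdx3, and the caudal covariate 0.12 for Sod2. In E against P the caudal covariate gave -0.067 for Sod2, 0.087 for Sod3 and -0.00064 for Ccs, and removal of trends -0.016 for Ccs. Without single libraries the values ran, in P against H, from -0.0054 to 0.15 for Gpx3, -0.10 to 0.060 for Prdx4, -0.085 to 0.072 for Txnrd2 and -0.26 to 0.060 for Ccs. In C against P they ran from -0.14 to 0.10 for Sod2, -0.0047 to 0.063 for Prdx3 and -0.35 to 0.11 for Prdx6. In E against P they ran from -0.038 to 0.12 for Sod1, -0.041 to 0.20 for Sod2, -0.26 to 0.19 for Sod3, -0.076 to 0.018 for Gpx4, -0.082 to 0.019 for Prdx3 and -0.075 to 0.090 for Ccs. The cause was not tested.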

Other observations

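The relations of motor neuron genes with microglia and with the Hox score were chosen as tests after library values had been seen. The relation of the caudal with the rostral Hox score was fixed before the rostral values were seen.

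Hox genes, which mark position along the cord, differed between libraries of 1 group. Hoxd10 had 0.0318 FPKM in H4 and 7.28 in H1, 0.351 in P66 and 18.8 in P74, and was listed at 0 in C84 against 3.65 in C85. Hoxc11 was listed at 0 in H4, P66 and C84 and had 10.1 FPKM in E90. Single rostral Hox genes were mixed. Hoxb8 had 88.8 FPKM in H4 and 41.3 in H1, and Hoxc8 38.8 and 20.9, but Hoxb8 had 51.6 in P66 and 53.2 in P74.

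A hypothesis is that the pieces of lumbar cord may have been taken at different levels. Within groups over 12 libraries, the caudal score fell as the rostral score rose (r = -0.706, permutation p = 0.00157, adjusted 0.00657 over 6 relations, rho = -0.671, permutation p = 0.0133, r = -0.648 without the 2 farthest), as that hypothesis requires. The caudal score had r = 0.808 with the motor neuron score (permutation p = 0.0302, adjusted 0.0603, rho = 0.699, permutation p = 0.0576, r = 0.535 without the 2 farthest), which did not pass after adjustment. With the Schwann cell score it had r = 0.480 (permutation p = 0.145, adjusted 0.174, rho = 0.413, permutation p = 0.194, r = 0.311 without the 2 farthest).

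Among the 9 ALS model libraries, a hypothesis was that libraries with a stronger response of disease-associated microglia have lower motor neuron scores. The exact test gave rho = -0.183 (p = 0.644) and r = -0.402 (p = 0.283, adjusted 0.283 over 6 relations), and r was 0.648 without the 2 farthest libraries, so the sign rests on those libraries. The scores were not taken as deviations from group means here, so group differences enter these values. The 9 libraries do not decide the question.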
